A study of Mus musculus with 16 samples.

How the data were processed

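RNA of male C57BL/6 mice, 10 weeks of age, was sequenced from quadriceps and brown fat as 16 libraries, 4 per genotype in each tissue. The labels' protocols describe stranded mRNA libraries read from one end. The submitters' processing notes name STAR 2.5.1b, the mouse build mm9 and DESeq2 1.10.1, without saying which step each one served. The gene annotation and the read counter are not given in the sources used here, so genes that share reads with near-identical copies or overlapping genes may be counted differently from other pipelines.

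Each tissue has one table of the authors' comparison between genotypes, and no values per library were analysed here. Per the file headers, each gene has a mean normalized count, which is treated as a signal over all 8 libraries of the tissue and was made by the authors. The deposited log2 fold change and its standard error are on the log2 scale. The deposited Wald statistic, a score, is that fold change divided by its standard error. The deposited p-value and adjusted p-value follow from that score. Recomputing the statistic, the two-sided p-value and the Benjamini-Hochberg adjustment from the deposited columns returned the deposited values to rounding.

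The deposited log2 fold changes behave as shrunken estimates, since the standard error falls towards 0 in genes of low mean count. Its median was 0.0223 in quadriceps and 0.0181 in brown fat for genes with a mean under 1, against a maximum of 0.135 and 0.127. Fold changes printed here may therefore be smaller than unshrunken ones. The shrinkage is inferred from the values and no header states it.

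Neither table's header says which genotype is the numerator. The order in which the tables name the genotypes was read as numerator first, which is an assumption for both tissues. The tables name them in opposite orders, so the brown fat sign was turned to give uORF-TAA over wild type in both. If the assumption fails for one tissue, every direction in that tissue and every comparison of directions between tissues turns over. If it fails for both, all directions turn over and the comparisons between tissues stand.

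Changed genes were those with a deposited adjusted p under 0.05. The brown fat table gives an adjusted p for 9272 of 17973 genes with a p-value, and the 8701 others lie at lower mean counts. The quadriceps table gives one for all 17521 genes with a p-value. The design written before the data were examined foresaw this case and used the deposited test. Gene lists, 40 in all, were fixed before the data were examined. They were tested with cameraPR of limma 3.58.1 in R 4.3.3, on the Wald statistics of all genes with a p-value. The test was two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 38 lists with at least 5 measured members. An estimated correlation needs values per library, so a preset correlation of 0.05 was the stricter alternative. The list p-values compare members with the other genes and do not measure how a list varies among mice. Differences between tissues were tested per gene as the difference of the log2 fold changes over the root of the summed squared standard errors, with a two-sided normal p. That test treats the tissues as independent. It uses the deposited values, which behave as shrunken, so a gene of low mean count in either tissue enters with a small standard error there. The labels do not say whether both tissues came from the same mice.

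Genes were named by a rule fixed before the data were examined. Per tissue these are Ppargc1a and the changed genes with a mean of at least 50, up to 12 in each direction, filled to 10 by smallest p where fewer than 10 changed. Per list they are up to 4 members of smallest p. Between tissues they are up to 10 genes of smallest adjusted p for the difference. Genes outside the rule are named only where the text says so. Some genes that the rule picks are not reported here.

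Depth per library, the product of the size factor and the summed mean counts, was recovered from genes with a single read in a single library, whose mean normalized count is fixed by that library's size factor. In each tissue 8 levels stood out, each shared by at least 61 genes in quadriceps and 69 in brown fat. Size factors ranged from 0.543 to 1.51 in quadriceps and from 0.859 to 1.39 in brown fat, and were not assigned to samples. Symbols were compared with a GRCm38.p6 gene table, in which 17574 of the 18657 symbols were current and 18568 matched with synonyms. No coordinates are given, since that build differs from mm9. Transcript length and GC content were found for 98.9% of genes in each tissue.

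The procedures were tested on simulated statistics first. Of genes shifted by 5 standard errors, 90% were recovered in the quadriceps simulation of 17521 genes and 95% in the brown fat simulation of 17973 genes. Of those shifted by 3 standard errors, 40% and 27% were recovered. One shifted list was called in each simulation (adjusted p = 0.00124 and 0.00168), with 0 calls among the 37 other lists. The shift given to each member of that list was larger in size than the mean Wald statistic of most lists called below. Recovery of smaller list shifts was therefore not tested. The simulated statistics were independent standard normal draws, so these runs do not show how often lists of correlated genes are called falsely. The deposited Wald statistics spread less, with standard deviations of 0.809 in quadriceps and 0.796 in brown fat. The brown fat simulation adjusted over all 17973 genes, while the deposited adjustment covers 9272. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Alternatives covered thresholds, adjustments, an empirical null, filters on mean count, the list test's settings, trends with mean count, length and GC content, and the direction of the brown fat table.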

Results

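The mice were homozygous for an allele of Ppargc1a labelled uORF-TAA and were compared with wild-type littermates. Ppargc1a encodes the transcriptional coactivator PGC-1alpha, uORF stands for upstream open reading frame, and TAA is a stop codon. A uORF is a short reading frame ahead of the main coding sequence. Quadriceps muscle and brown adipose tissue were profiled by mRNA sequencing at 10 weeks of age, with 4 libraries per genotype in each tissue and 16 in all. The tables listed 17539 genes in quadriceps and 18000 in brown fat. The estimated depth per library ran from 11.4 to 31.8 M counts (M, mega) in quadriceps, with a median of 22.0 M, and from 11.0 to 17.8 M in brown fat, with a median of 11.7 M. Fold changes are given as uORF-TAA over wild type, under the assumption that each table names its numerator first. Errors are the standard errors of the authors' deposited table.

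The first question was whether the mRNA of the mutated gene differed between genotypes. Ppargc1a did not pass the test in either tissue. Its log2 fold change in quadriceps was 0.06 ± 0.13 (SE) in the authors' deposited table, at a mean normalized count of 604 and an adjusted p of 1.00. In brown fat the authors' deposited table gave 0.0016 ± 0.11 (SE) at a mean normalized count of 894, also with an adjusted p of 1.00. The 95% interval in quadriceps, on the shrunken log2 scale, ran from -0.19 to 0.31.

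In quadriceps, 0 genes passed an adjusted p of 0.05 in the deposited DESeq2 test, and 350 had an unadjusted p under 0.05, with 165 higher and 185 lower in uORF-TAA. The genes of smallest p are given as values and not as changes. Myod1, a transcription factor of muscle progenitors, had a log2 fold change of 0.61 ± 0.13 (SE) and an adjusted p of 0.0960 in the authors' deposited table. Slc4a4, a sodium bicarbonate cotransporter, and Dusp6, a phosphatase of ERK kinases, had log2 fold changes of 0.54 and 0.52 in the authors' deposited table. Hs3st5 had 0.49 there. On the lower side the authors' deposited table listed Prrg3 at -0.46, Mrgprg at -0.43, Ankzf1 at -0.40, the RNA-binding protein gene Hnrnpa1 at -0.40 and the mRNA export factor gene Nxf1 at -0.29. With an empirical null, 13 genes passed, 5 higher and 8 lower.

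In brown fat, 8 genes passed an adjusted p of 0.05, 2 higher and 6 lower in uORF-TAA under the assumed reading of the table. Zbtb16, a zinc finger transcription factor induced by glucocorticoids, fell most, with a log2 fold change of -0.82 ± 0.13 (SE) and an adjusted p of 1.06e-06 in the authors' deposited table. Pik3ip1, an inhibitor of phosphoinositide 3-kinase, fell by 0.66 ± 0.10 (SE) on the log2 scale in the authors' deposited table. Spsb1 fell by 0.54, the ubiquitin ligase gene Cblb by 0.49, 8430408G22Rik by 0.48 and the transcription factor gene Klf13 by 0.42 in the authors' deposited table. The current symbol of 8430408G22Rik is Depp1, a gene induced by FOXO factors. Apold1, an endothelial gene, rose by 0.60 ± 0.13 (SE), and Lama4, a laminin chain of basement membranes, by 0.32 ± 0.07 (SE) in the authors' deposited table. The next genes by p did not pass. Ucp3, a mitochondrial carrier, had a log2 fold change of 0.33 and an adjusted p of 0.0744 in the authors' deposited table, and the transcription factor gene Sox4 had -0.49 and 0.0990. Counts depended on the threshold, with 4 genes at an adjusted p of 0.01 and 76 with an empirical null. Adjusted over every gene with a p-value, Spsb1 (adjusted p = 0.0562) and Cblb (0.0665) no longer passed.

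**Figure D1:**
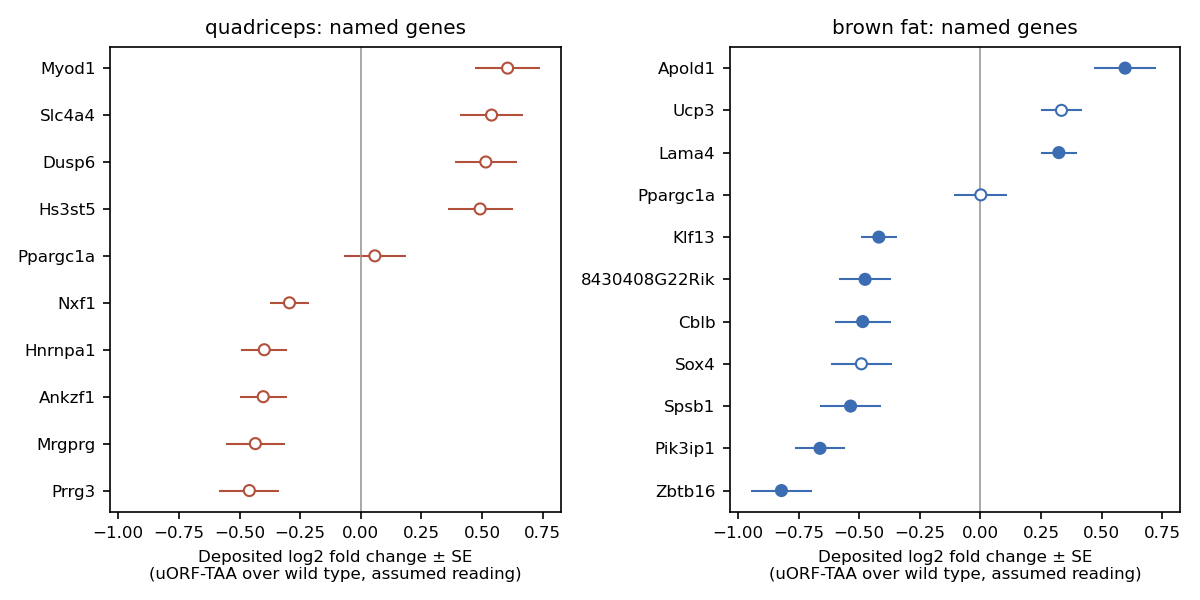
Deposited log2 fold change (x axis, uORF-TAA over wild type under the assumed reading), with bars of 1 SE, in quadriceps on the left and brown fat on the right. Shown are Ppargc1a and the changed genes or genes of smallest p given above for each tissue, without the members named from gene lists. Filled points passed an adjusted p of 0.05, which 0 genes did in quadriceps and 8 did in brown fat.

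Among the fixed gene lists in quadriceps, 6 of 38 were called, 3 higher and 3 lower. Genes induced by glucocorticoids or fasting fell as a list, with 14 of 15 measured members below 0, a mean Wald statistic of -1.43 and an adjusted p of 2.15e-09 with limma's cameraPR. Of these members 3 had an unadjusted p under 0.05, and 0 passed when adjusted over the list alone or over all genes. In the authors' deposited table Ddit4, an inhibitor of mTORC1, had a log2 fold change of -0.34 ± 0.13 (SE), the cell cycle inhibitor gene Cdkn1a -0.28, Foxo1 -0.27 and Cebpd -0.26. Markers of mural cells (smooth muscle and pericytes) fell with a mean Wald statistic of -1.31 and an adjusted p of 1.01e-05, 8 of 10 being below 0. Within it Myh11, the smooth muscle myosin, passed when adjusted over the list alone (adjusted p = 0.00476) with a log2 fold change of -0.35 ± 0.10 (SE) in the authors' deposited table, and 0 members passed over all genes. Tagln at -0.32, Acta2 at -0.29 and Mylk at -0.20 followed in the authors' deposited table. Peripheral nerve glia markers fell, with all 10 measured members below 0, a mean Wald statistic of -1.21 and an adjusted p of 4.67e-05. The myelin gene Mbp was at -0.20 in the authors' deposited table, and 0 members passed when adjusted over the list alone or over all genes.

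Fatty acid oxidation genes rose in quadriceps as a list, with 20 of 21 above 0, a mean Wald statistic of 0.76 and an adjusted p of 0.00147. No single member had an unadjusted p under 0.05, and 0 passed when adjusted over the list alone or over all genes. Adipocyte markers stood beside them with 11 of 12 above 0, a mean Wald statistic of 0.59 and an adjusted p of 0.0944, and were not called. The authors' deposited table gave Acsl1, which activates long-chain fatty acids, a log2 fold change of 0.21 ± 0.11 (SE) and Decr1 0.15. Secreted regulators of vessel growth rose, with 9 of 10 above 0 and an adjusted p of 0.0409. Vegfa had a log2 fold change of 0.28 ± 0.12 (SE) in the authors' deposited table. Fibroblast and matrix genes rose, with 12 of 15 above 0 and an adjusted p of 0.0363, and the collagen gene Col3a1 was at 0.24 in the authors' deposited table. In both of these lists 0 members passed when adjusted over the list alone or over all genes. With a preset correlation of 0.05 the vessel growth and matrix lists were lost (adjusted p = 0.132 for each), and the 4 others held. The vessel growth list was also lost with trends in mean count, length and GC content removed (adjusted p = 0.0536) and in the rank-based test (0.0595), and the matrix list among genes with a mean of at least 10 (0.0773). Genes widely used as PGC-1alpha targets were not called in quadriceps, with 16 of 23 above 0 and an adjusted p of 0.0810.

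In brown fat 16 of 38 lists were called, 13 higher and 3 lower in uORF-TAA under the assumed reading. The glucocorticoid and fasting list fell, with 13 of 15 members below 0, a mean Wald statistic of -1.30 and an adjusted p of 8.68e-08. Zbtb16 was the one member past the threshold over all genes, and the mean of the other 14 was -0.93. With all 8 changed genes of brown fat left out of the test, Zbtb16 among them, the list's adjusted p was 4.90e-04. Adjusted over the list alone, 2 members passed, against 1 over all genes. These were Zbtb16 and Foxo1, a transcription factor active in fasting, which had a log2 fold change of -0.41 ± 0.12 (SE) in the authors' deposited table. Peripheral nerve glia markers fell, with 9 of 10 below 0 and an adjusted p of 0.00202. Adjusted over the list alone 1 member passed, and 0 passed over all genes. Circadian clock genes fell, with 13 of 19 below 0 and an adjusted p of 0.00496, and 0 members passed when adjusted over the list alone or over all genes. Nr1d1, a repressor of the clock, was at -0.34 ± 0.12 (SE) in the authors' deposited table.

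PGC-1alpha target genes rose in brown fat under the same reading, with 18 of 23 above 0, a mean Wald statistic of 0.77 and an adjusted p of 5.63e-04. Adjusted over the list alone 3 members passed, against 0 over all genes. In the authors' deposited table Dio2, which activates thyroid hormone, had a log2 fold change of 0.48 ± 0.12 (SE), Ppara 0.41 ± 0.12 (SE) and Ucp3 0.33 ± 0.08 (SE). The thermogenesis list rose with an adjusted p of 0.0105 and 18 of 22 above 0. Several of its members, Dio2 and Ppara among them, also belong to the previous list, so the 2 calls are not independent. Dio2 and Ppara were the 2 members that passed when adjusted over the list alone, with 0 over all genes. Neither list was tested without them, so how far these few genes carry the 2 calls is not known. The median log2 fold change in brown fat was 0.042 over the PGC-1alpha target list and 0.045 over the thermogenesis list. In the thermogenesis list 1 member was lower at an unadjusted p under 0.05. General adipocyte markers rose with an adjusted p of 0.00293 and 10 of 12 above 0, beside the metabolic lists that follow. These were fatty acid oxidation (adjusted p = 0.00947, 20 of 21 above 0), the TCA cycle and pyruvate dehydrogenase (0.0197, 17 of 18), complex I (0.0197, 32 of 35), the mitochondrial ribosome (0.0270, 60 of 76), lipogenesis (0.0263, 11 of 16) and lipolysis (0.0202, 9 of 11). In each of them 0 members passed when adjusted over the list alone or over all genes. The authors' deposited table gave the adipocyte regulator gene Cebpa a log2 fold change of 0.23, Thrsp of the lipogenesis list 0.34 and Lipe, the hormone-sensitive lipase, 0.17. Fibroblast and matrix genes (adjusted p = 0.00638, 12 of 16 above 0), immediate early genes (0.00496, 13 of 15), interferon-stimulated genes (0.0106, 14 of 18) and slow fibre genes (0.0202, 13 of 15) rose too, with 0 members past the threshold over the list alone or over all genes. The fast fibre and muscle fibre lists of brown fat leaned lower without being called, with 13 of 14 and 16 of 18 members below 0. With a preset correlation of 0.05, 7 of the 16 lists held and 9 were lost, namely fatty acid oxidation (adjusted p = 0.0733), interferon (0.0733), thermogenesis (0.0755), lipolysis (0.0755), the TCA cycle (0.0837), slow fibre (0.0837), lipogenesis (0.102), complex I (0.136) and the mitochondrial ribosome (0.277). The PGC-1alpha target list held (0.0184). The rank-based test lost lipogenesis (adjusted p = 0.0754). Among genes with a mean of at least 10, lipogenesis (0.0563) and the mitochondrial ribosome (0.0813) were lost. Ranking by log2 fold change lost slow fibre (0.158) and the mitochondrial ribosome (0.0531). With trends in mean count, length and GC content removed, 8 lists held, and those lost were fatty acid oxidation (adjusted p = 0.0795), thermogenesis (0.0532), lipolysis (0.173), the TCA cycle (0.128), slow fibre (0.0936), lipogenesis (0.156), complex I (0.248) and the mitochondrial ribosome (0.216).

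**Figure D2:**
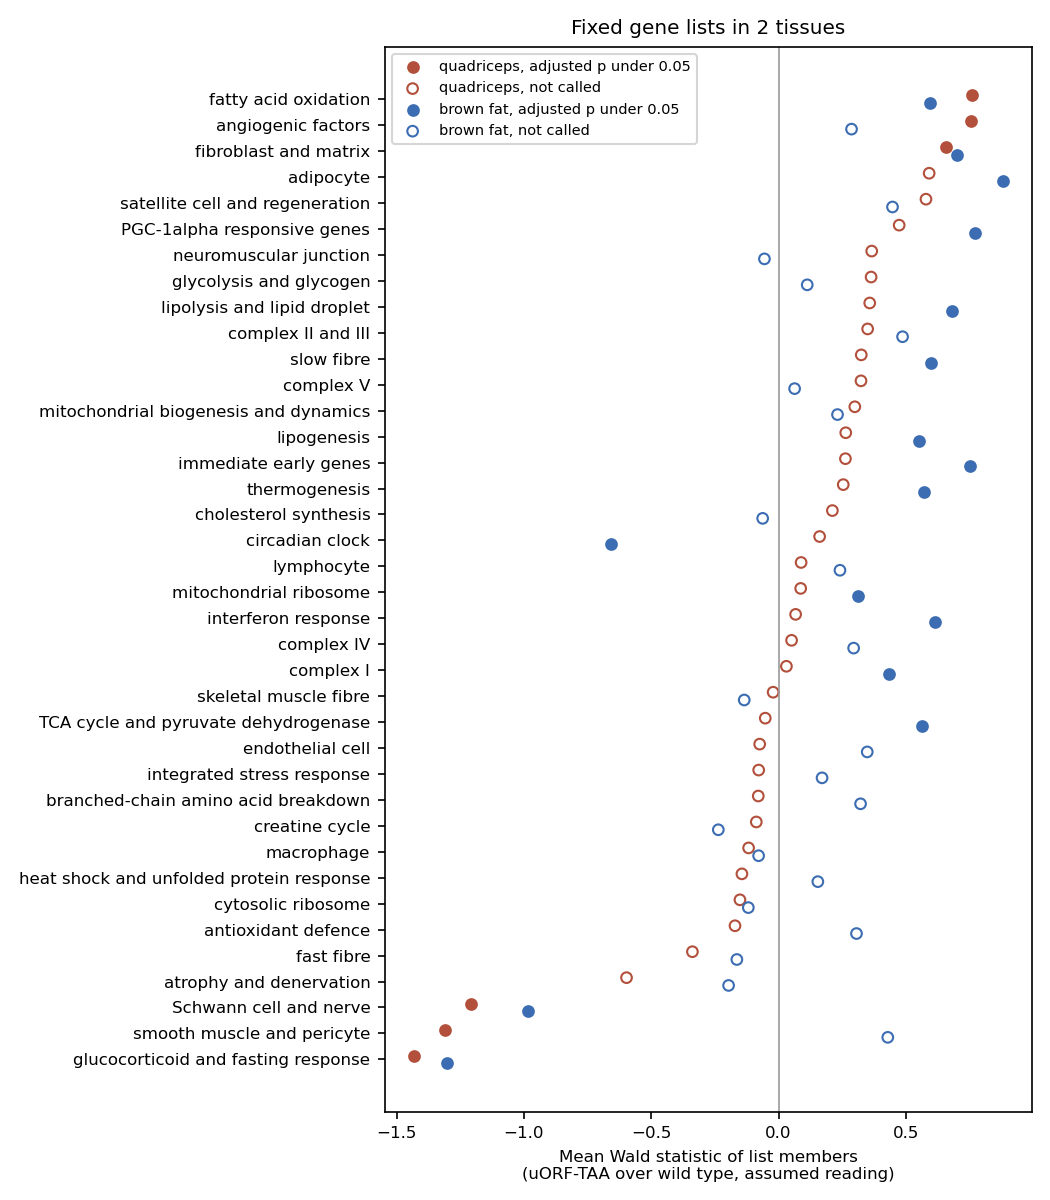
Mean Wald statistic of the members of each fixed list (x axis, uORF-TAA over wild type under the assumed reading) in quadriceps (red) and brown fat (blue), with filled points for lists called at an adjusted p of 0.05. The glucocorticoid and fasting list lies lowest in both tissues, at -1.43 and -1.30, although in brown fat it stands at -0.93 without Zbtb16, against -0.98 for the nerve glia markers.

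The tissues were then compared. No gene passed the test of the difference (0 of 16844 at an adjusted p of 0.05, and 195 at an unadjusted p under 0.05, by the normal test of the difference of fold changes). The smallest adjusted p was 0.905, which Slc4a4 and Myod1 had. Myod1 had a mean normalized count of only 5.19 in brown fat, where its standard error was 0.0755. Of the fixed lists 1 differed, the mural cell markers, with a mean difference statistic (quadriceps less brown fat) of -1.26 and an adjusted p of 8.76e-06 with limma's cameraPR. Its mean Wald statistic was -1.31 in quadriceps and 0.43 in brown fat, where it was not called (adjusted p = 0.228). The rank-based version of the test called 0 lists, with an adjusted p of 0.0706 for this one. The PGC-1alpha target list did not differ (adjusted p = 0.453), although it was called in brown fat alone. These comparisons depend on the relative reading of the tables, and with the brown fat table read the other way 6 genes and 14 lists differed. The mural cell list was called in that reading too, in the same direction.

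No gene passed the threshold in both tissues (0 in quadriceps, 8 in brown fat). At an unadjusted p under 0.05 in each, 21 genes were lower in both, against 2.24 expected of independent lists (Fisher's exact test over genes, two-sided, p = 8.59e-15), and 2 were higher in both, against 1.57. Opposite directions were taken by 3 genes, against 3.75 expected of independent lists. Of the first 5 genes by the larger p of the tissues, Mrgprg is named by the rule, and the 4 others are outside it and were chosen after their values were seen. In the authors' deposited table Mrgprg had log2 fold changes of -0.43 in quadriceps and -0.44 in brown fat, Rsrp1 -0.38 and -0.34, Myzap -0.32 and -0.36, Hif3a -0.34 and -0.41, and Lrrc8c -0.40 and -0.30. Across the 16844 genes the Wald statistics of the tissues had a Spearman's rho of 0.153, and 0.210 over 9275 genes with a mean of at least 50 in both. Genes are not independent replicates, and libraries from the same mice would share chance differences. Read the other way, the brown fat table gives rho = -0.153.

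**Figure D3:**
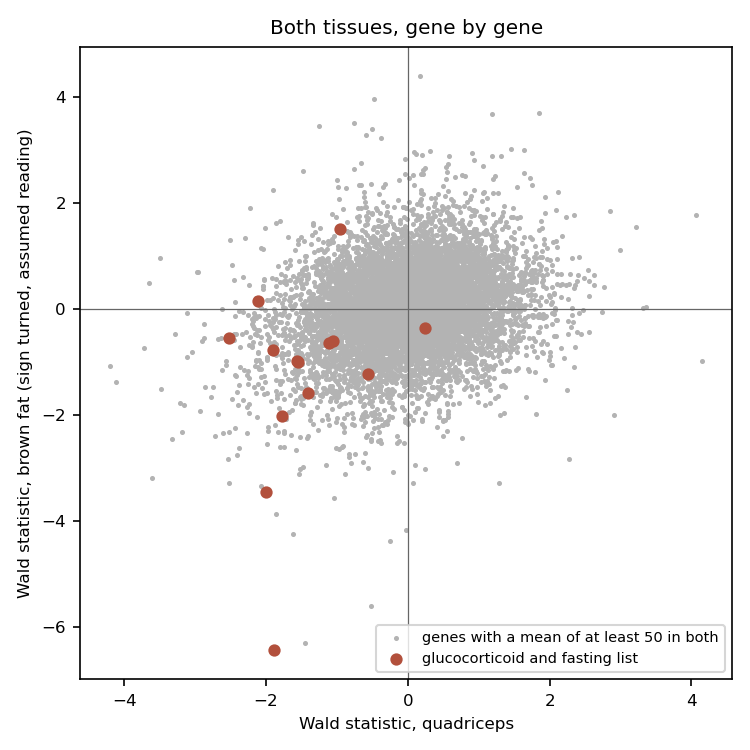
Wald statistic of each gene in quadriceps (x axis) and brown fat (y axis, sign turned under the assumed reading), for 9275 genes with a mean of at least 50 in both tissues. Red points are members of the glucocorticoid and fasting list, most of which lie below 0 on both axes.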

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

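The tests of time of day, of feeding or stress state and of low counts were chosen only after the result was seen. The mural cell marker list differed between the tissues by a test of the difference itself (adjusted p = 8.76e-06), a result that the rank-based test did not call.

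Genes of the glucocorticoid and fasting list were lower in both tissues under the assumed reading of the tables, with mean Wald statistics of -1.43 and -1.30. Trends with mean count, transcript length and GC content do not account for it, as the larger adjusted p of the tissues was 4.47e-07 after their removal. Time of dissection stays open, since the Bmal1 arm less the Dbp and Per arm of the clock gave -1.50 ± 0.60 (SE over genes) in quadriceps and 0.0175 ± 0.60 in brown fat, where the clock list was called lower (adjusted p = 0.00496). A small difference between the arms in either tissue had been written as speaking against this explanation, and the brown fat value met that bound. It did not do so by more than its spread, a margin added to the written bound, so it was not counted. Cell composition stays open, since the marker list that moved most reached 0.984 in size in brown fat, for nerve glia, and a mean of -1.31 in quadriceps, for mural cells, while the fasting list of brown fat stood at -0.93 without Zbtb16. Feeding or stress state cannot be told apart from genotype either. The lipogenesis list, which feeding raises, was called higher in brown fat (adjusted p = 0.0263), against the fasting list, but was not called in quadriceps (0.483). The brown fat call was lost with a preset correlation of 0.05 (0.102) and in the rank-based test (0.0754). It was also lost among genes with a mean of at least 10 (0.0563) and with the trends removed (0.156). Stress was not probed by this list. An effect of the mutation itself remains a hypothesis beside feeding and stress.

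The Wald statistics of the tissues correlated across genes. Removal of the trends left a Spearman's rho of 0.158, and leaving out every member of the fixed lists left 0.148, so neither accounts for the correlation. Shared animals stay open, because the labels do not say whether both tissues came from the same mice and no values per library were analysed here. The genotype is a further open explanation, and it was not tested apart from the animals.

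In both tables the p-values crowded towards 1, with medians of 0.571 in quadriceps and 0.599 in brown fat. Discrete low counts do not account for this, since the standard deviation of the Wald statistic stayed at 0.833 or less among genes with a mean of at least 100. The dispersion estimates of the authors' fit stay open, and no biological explanation was tested.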

How the results depend on the processing

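The alternatives that remove trends, that leave out the called genes, or that read the brown fat table the other way were chosen after seeing the data. No paired analysis was possible because the tables hold no values per library. For the same reason count models, filters on counts, pseudocounts, a replicate block, leaving out each replicate, an estimated correlation, an interaction model and other splits of the samples were not run, so the hold of any single mouse on a result is unknown. Ppargc1a stayed above the threshold in both tissues under each alternative run. Changed genes numbered 0 in quadriceps and 8 in brown fat. In quadriceps they became 2 at an adjusted p of 0.1 and 13 with an empirical null. In brown fat they became 4 at an adjusted p of 0.01, 3 with at least a 1.5-fold change, 4 with Bonferroni adjustment and 76 with an empirical null. The 1.5-fold bound was applied to the deposited fold changes, which behave as shrunken, so more genes might pass it unshrunken. The thresholds explain the smaller counts, and the empirical null narrows the assumed spread by its own construction. The 16 lists of brown fat became 7 with a preset correlation of 0.05, 9 with the trend in mean count removed and 8 with the trends in mean count, length and GC content removed. Each list called in the main test kept its direction in these settings. The 1 list that differed between tissues became 2 with a correlation of 0, 2 with the difference of Wald statistics, 0 with the rank-based test and 14 with the brown fat table read the other way. That reading also gave 6 genes in place of 0 for the tissue difference. The overlap of 0 genes became 23 in the same direction at an unadjusted p of 0.05, and 3 at that threshold with the brown fat table also read the other way. The Wald statistics of brown fat had a Spearman's rho of 0.086 with mean count, -0.093 with length and 0.102 with GC content. The brown fat lists lost when trends were removed are therefore not separated from those trends. The cause of the other changes in list counts was not tested. The smallest mean count of a brown fat gene with an adjusted p was 105.6 in the authors' table, and adjustment over every gene with a p-value gave 6 changed genes there. What depth limits was not tested.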

Other observations

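Tissue identity showed in the levels. Genes of the muscle fibre list took 26.2% of the summed mean counts in quadriceps and 1.16% in brown fat, while adipocyte list genes took 2.82% in brown fat and 0.147% in quadriceps. The muscle fibre list was not called in either tissue (adjusted p = 0.875 in quadriceps and 0.557 in brown fat), nor was the fast fibre list (0.347 and 0.551). Macrophage (0.722 and 0.756), lymphocyte (0.875 and 0.423) and endothelial markers (0.799 and 0.249) were not called in either tissue.

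Several groups tied to mitochondria and stress were likewise not called, with adjusted p in quadriceps and then brown fat. These were complex II and III (0.391 and 0.0890), complex IV (0.952 and 0.360), complex V (0.391 and 0.796), mitochondrial biogenesis and dynamics (0.391 and 0.377), the integrated stress response (0.799 and 0.551) and antioxidant defence (0.547 and 0.254). No symbol starting with mt- was listed in either table. The erythroid list had 3 measured members, too few for the list test, and all 3 were above 0 in both tissues. In brown fat, under the assumed reading, Alas2 of this list, the first enzyme of heme synthesis, had a log2 fold change of 0.34 ± 0.13 (SE) in the authors' deposited table and passed when adjusted over the list alone (adjusted p = 0.0252), with 0 passing over all genes.

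Myod1 passed when adjusted over the satellite cell and regeneration list alone in quadriceps (adjusted p = 5.98e-05), although the list itself was not called (0.190). Over all genes its adjusted p was 0.0960. In other uncalled lists, 1 higher and 1 lower immediate early gene of quadriceps passed over the list alone (smallest adjusted p = 0.0391). So did 1 lower heat shock and unfolded protein response gene of brown fat (0.0442). Adjustment over a list alone does not correct for the number of lists. The genes at an unadjusted p under 0.05 in both tissues that went in opposite directions were Nr1d1, Zbtb38 and Bhlhe40, which were named after their values were seen. Their number did not exceed the 3.75 expected of independent lists. Nr1d1 and Bhlhe40 belong to the clock list, whose tissue difference had an adjusted p of 0.0568.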
